A study of Mus musculus with 2 samples.

How the data were processed

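Gene expression was measured on 2 Affymetrix mouse expression arrays, 1 per genotype. Per the labels, total RNA came from the cerebral cortex of 1 wild-type embryo and of 1 Sox11-null littermate at embryonic day 17.5, on a mixed C57BL/6 and 129 background. The RNA was turned into biotinylated cRNA before hybridisation, per the labels' protocols. No culture, pool or second animal stands behind either genotype, so the arrays give 1 value per gene and genotype, and no variance between embryos.

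The deposited table holds 1 signal intensity per probe set and array, on a linear scale. Affymetrix Expression Console is the program given in the submitters' processing notes. The summary algorithm, its version and any filter are not given in the sources used here. Each array had the same mean over the deposited intensities after trimming 2% at each end, 500 (wild type 500.002, Sox11 null 500.002), as scaling each array by 1 factor to a common target gives. Such scaling would leave intensity-dependent differences between arrays in place, and low intensities are noisy and reach 0.0736 and 0.0592. No detection call was used here, so the limit of detection is not known from the arrays themselves. The number of arrays limits the precision of every value.

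The table lists 45101 probe sets. The 64 control probe sets were left out. Of the others, 34945 name 1 gene in the platform annotation, 932 name several genes and 9160 are unnamed here. Symbols of 34741 single-gene probe sets were updated by gene number through a RefSeq gene table of the GRCm38.p6 assembly, and 204 kept the symbol of the annotation. That table was used for symbols, for chromosome membership and for the order of genes, and no coordinate is given because the sources name no genome build. Each gene was represented by its probe set with the highest mean log2 signal, which gave 18193 genes. A gene counted as measured when its signal on at least 1 array reached that array's median over all non-control probe sets (177.5 for wild type, 177.4 for Sox11 null), which held for 12390 genes.

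Signals were taken to log2. The Sox11-null array was shifted so that the median difference over measured genes was 0, a shift of -0.020. Values below the 25th percentile of their array (52.9 and 52.5) were then raised to that percentile, and a fold with 1 value at this floor is given as a lower bound. All differences are Sox11 null minus wild type. With 1 array per genotype no test was run on any gene and no p-value is given for it. Genes were instead counted at fixed sizes of 1.5-fold and 2-fold. A 2-fold difference therefore describes these 2 libraries, not the genotypes.

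As a technical yardstick, the log2 differences of different probe sets of the same gene were compared over 5155 genes with several measured probe sets (13427 probe sets). Their pooled SD was 0.39. The central 95% of differences ran from -0.94 to 0.82 in the lowest of 3 equal groups of measured genes by level (4130 genes each), from -0.49 to 0.57 in the middle group and from -0.46 to 0.45 in the highest. These ranges hold biological and technical differences together and do not replace replicates.

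There were 33 gene lists fixed before the data were examined, and 19 lists of tissues and sex-linked genes were added after the first results were seen. Each list is described by the number of its measured members beyond 1.5-fold and by its median difference. The percentile of that median was taken among 10000 random lists of the same size, matched on mean level in 20 bins. The percentile describes these libraries and is not a p-value. The rule for named genes was also set in advance. It takes every Sox11 probe set with Sox4 and Sox12, the 12 largest differences each way among genes above the floor on both arrays, up to 5 bounds each way, up to 3 members of each list beyond 1.5-fold each way (or the 2 brightest where none is), and Xist with the Y-linked genes. Genes without a standard symbol were passed over. Other genes named in the text are members of the lists or of gene families, chosen after their values were seen.

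The comparison was tested on simulated data built from the real mean levels and a noise by level. In that simulation of Sox11 null against wild type over 12420 measured genes, 97 of 100 genes changed by 1.5 on the log2 scale and 100 of 100 changed by 3 were found beyond 2-fold. Of 12200 unchanged genes, 72 were also beyond 2-fold. The noise was Gaussian, drawn for each probe set alone, with its SD from the median absolute deviation of the same 2 arrays' differences by level. That SD includes real differences shared by many genes, but large differences of a few genes hardly affect it. The 72 genes can therefore be too few, and they give no error rate for the real counts.

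The alternatives were no centring, quantile normalization, removal of a loess trend on level, no floor or a floor at the median, no filter or a filter at the 75th percentile, the mean over all probe sets of a gene, and leaving out probe sets of the _s_at and _x_at types. The mean over all probe sets took in unmeasured ones, with the floor applied after averaging. Counts without genes of the X and Y chromosomes and without epithelial gene families were added after the data were seen. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.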

Results

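The data compared an RNA sample labelled as cerebral cortex of a Sox11-null mouse embryo with one labelled as cortex of a wild-type littermate, both late in embryonic development. Sox11 encodes a transcription factor of the SoxC group, and the comparison asks which cortical genes differ without it. Each genotype was represented by 1 array of 1 embryo, so every difference below is a difference between 2 libraries, with no replicate check. The log2 signals of the libraries correlated across the 12390 measured genes (Pearson r = 0.970, with genes not being independent replicates). The ratio of 3' to 5' signal of the beta-actin control, a sign of RNA integrity, was 1.78 in the wild-type and 1.16 in the Sox11-null library, and that of Gapdh was 0.922 and 0.816.

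Sox11 was lower in the Sox11-null library with each of its 6 probe sets, and signal remained with all of them. The brightest probe set, 1453125_at, gave 6582 in wild type and 3149 in the null library, which is 47.8% of the wild-type signal and a log2 difference of -1.04. The lowest share remained with 1431225_at, at 3893 and 637 (16.4%, log2 difference -2.59), followed by 1453002_at at 5252 and 924 (17.6%, -2.49). The other probe sets kept 29.5% (1436790_a_at), 35.8% (1429051_s_at) and 45.1% (1429372_at). The mean log2 difference was -1.74 ± 0.67 (SD over 6 probe sets of the same 2 RNA samples). The 2 other SoxC genes were within 1.5-fold. Sox4 was at 12634 and 14580 (log2 difference 0.23), and Sox12 was at 923 and 1023 (0.17, with -0.30 by its other measured probe set). Of the measured genes, 110 had a difference at least as negative as that of the brightest Sox11 probe set. Which probe sets lie in the deleted part of the gene is not given in the sources used here, so a probe set outside it would not check the genotype.

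**Figure D1:**
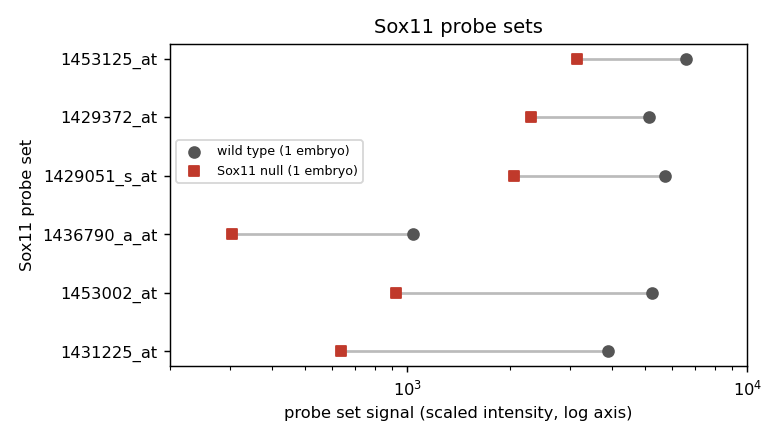
Signal of each Sox11 probe set (vertical axis) in the wild-type library (circles) and the Sox11-null library (squares), as scaled intensity on a log axis; each point is 1 array. All 6 null values lie below the wild-type values, at 16.4% to 47.8% of them.

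Both libraries, labelled as cortex, held high signals of genes of tissues outside the brain. Skeletal muscle genes were among the brightest on both arrays. The muscle actin Acta1 was at 23182 in wild type and 23519 in the null library, fast troponin C (Tnnc2) at 22674 and 22146, and the creatine kinase Ckm at 17849 and 16405. The salivary gland secretory genes Bpifa2 (21963 and 17131) and Smgc (17176 and 12281) were in the same range. The epidermal keratin Krt1 was at 9172 and 3465, the lens crystallin Cryba1 at 8494 and 5275, the bone sialoprotein gene Ibsp at 7576 and 7860, the enamel gene Amelx at 2009 and 1315, and growth hormone (Gh), a pituitary product, at 4615 and 1894. Of trunk organ genes, albumin (Alb) was at 125 and 80.3, and alpha-fetoprotein (Afp) at 10.4 and 9.33. Over lists added after the first differences were seen, and pooled after their own values were seen, 75 of 95 genes (78.9%) of 7 head tissue lists (muscle, epidermis, salivary and lacrimal glands, lens and retina, teeth, cartilage and bone, tongue) were above the median signal of both arrays, against 3 of 41 genes (7.32%) of 5 lists of trunk organs and posterior Hox genes. With the pituitary, olfactory and cochlear lists, which the first tally leaves out, the share was 74.6%. Muscle (15 genes), epidermis (37) and cartilage and bone (12) make up most of the first tally. These tissues lie in the trunk as well, so it is not a share of genes of the head alone. The trunk tally leaves out Ttr, which the choroid plexus expresses, and the heart list, whose genes embryonic skeletal muscle partly shares, and with both it was 7 of 50 (14%). Cortical neuron genes were present as well, with Neurod6 at 3019 and 2723 and Tbr1 at 554 and 483. The gene group comparisons below are comparisons of libraries with these signals, so a list named for a cortical cell type need not reflect those cells alone.

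**Figure D2:**
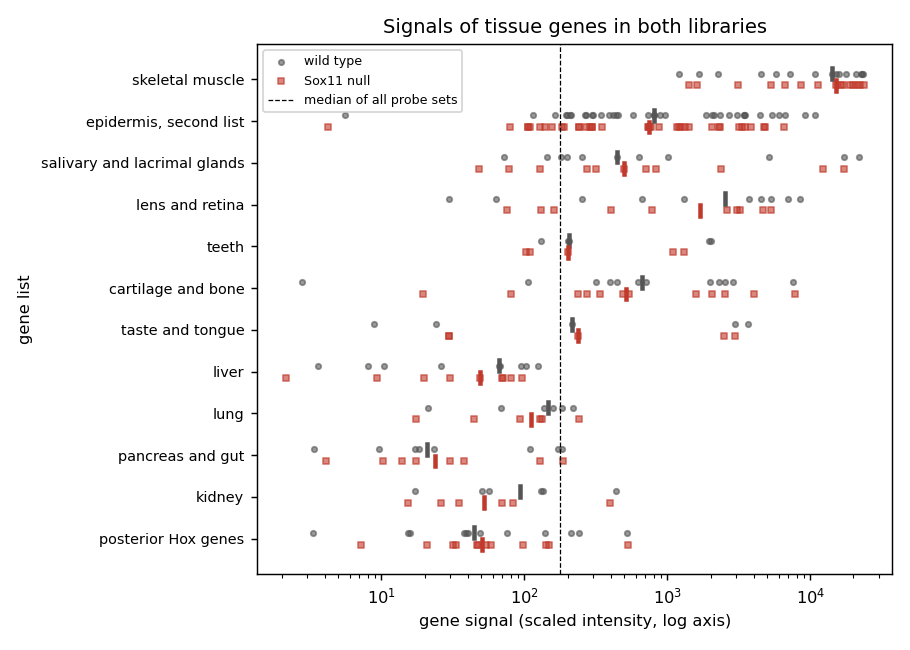
Signals of genes of 12 tissue and organ lists in the wild-type (circles) and Sox11-null (squares) libraries, as scaled intensity on a log axis; vertical bars are list medians, the dashed line is the median of all probe sets, and Ttr is left out of the liver list. Muscle genes reach 23519 in the null library, while the liver genes have medians of 66.1 and 48.8.

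More genes were 2-fold lower than 2-fold higher in the null library. Of the 12390 measured genes, 122 (0.985%) were at least 2-fold lower and 71 (0.573%) at least 2-fold higher. With all probe sets of a gene averaged the counts were nearer, at 147 lower and 139 higher. At 1.5-fold, 401 were lower and 380 higher. Of the 122 genes, 47 belonged to epithelial gene families (keratins, late cornified envelope, small proline-rich, kallikrein, mucin, crystallin and similar families, 189 measured genes), against 3 of the 71 higher genes. The family rule was written after the lower genes had been seen, and it goes by the start of the gene symbol, which takes in some unrelated genes. Without these families and without X- and Y-linked genes, 70 genes were 2-fold lower and 66 higher. The counts depend on dim genes, and with the floor at the array median 69 genes were 2-fold lower and 27 higher.

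Among genes above the floor on both arrays, each by its brightest probe set, Xist had the largest difference. This RNA, which coats the inactive X chromosome, was 112-fold lower in the null library (17505 and 155, log2 difference -6.80, but -5.35 without the _s_at and _x_at probe set types and -5.02 with all probe sets averaged). Among the other lower genes above the floor on both arrays, the largest differences were those of Lce3c, a late cornified envelope gene (9.34-fold lower, 619 and 65.4), and Prol1, a proline-rich gland gene (8.26-fold, 4196 and 501). Prpmp5, Zap70, a kinase of T-cell receptor signalling, S100a3 and Lce3a were 4.78 to 5.79-fold lower. Dcpp3, a gland secretory gene, was 4.54-fold lower (16907 and 3674), and its near-identical family members can share its probes. Cysrt1, the desmosomal cadherin Dsc1, the hair sheath keratin Krt25 and Bpifc were 4.07 to 4.53-fold lower. Among genes at the floor in the null library, Mucl2 was at least 6.13-fold, the hair sheath keratin Krt27 at least 5.83-fold, Cldn34c1 at least 4.78-fold, Fam178b at least 4.27-fold and Bves at least 4.12-fold lower. The sizes of the dimmer genes depend on the floor. With the floor at the median the log2 difference was -1.78 for Lce3c, -1.51 for Prpmp5, -1.63 for Lce3a, -0.83 for S100a3, -0.36 for Bpifc, -0.86 for Mucl2, -0.79 for Krt27, -0.50 for Cldn34c1, -0.34 for Fam178b and -0.29 for Bves. Without the _s_at and _x_at types Cysrt1 was at -1.68.

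Among genes higher in the null library and above the floor on both arrays, Tpsab1, a mast cell tryptase, was 12.4-fold higher (70.7 in wild type and 863 in the null library), and Zdhhc12, a protein palmitoyltransferase, was 5.73-fold higher (111 and 627). Gpr27, an orphan receptor, was 3.36-fold higher and Apobec3, a cytidine deaminase active against retroviruses, 2.96-fold. The tendon transcription factor gene Scx, Ccsap, Brinp2, the channel gene Hcn3, Muc4, Zfp593 and the dopamine receptor gene Drd1 were 2.46 to 2.79-fold higher. Zfp991 was 2.98-fold higher with its brightest probe set, but another measured probe set of it gave a log2 difference of -0.69. These sizes depend on the floor as well. With the floor at the median the log2 difference was 2.30 for Tpsab1, 1.84 for Zdhhc12, 0.28 for Gpr27, 0.22 for Apobec3, 0.73 for Scx, 0.996 for Ccsap, 0.14 for Brinp2, 0.28 for Hcn3, 0.17 for Muc4, 0.79 for Zfp593 and 0.092 for Drd1. With all probe sets averaged, Scx was at 1.01 and Zfp593 at 0.88. Among genes at the floor in wild type, the Y-linked genes Uty and Kdm5d were at least 11.8-fold and 8.55-fold higher, Ankrd9 at least 5.95-fold, Zfp112 at least 5.58-fold and Fcgbp at least 4.97-fold. With the floor at the median these were at 1.82, 1.35, 0.83, 0.73 and 0.57. Of the genes beyond 2-fold either way, 33 had another measured probe set, and in 21 of them the other probe sets had the same direction. In 14 of the 33 (42.4%, 95% Wilson interval 27.2% to 59.2%) the other probe sets differed in the same direction by 1.5-fold, against 471 of 5155 measured genes (9.14%).

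**Figure D3:**
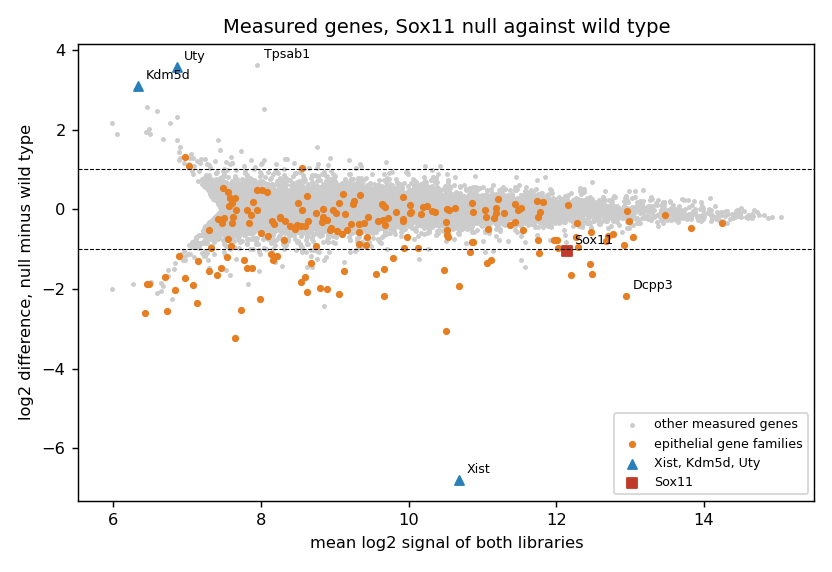
Log2 difference (Sox11 null minus wild type, vertical axis) against the mean log2 signal of both libraries for the 12390 measured genes; dashed lines mark 2-fold, and colours mark epithelial gene families, Xist with 2 Y-linked genes, and Sox11. Of the 189 genes of epithelial families, 47 are at least 2-fold lower and 3 at least 2-fold higher.

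Genes of neural progenitors and of the cell cycle were mostly within 1.5-fold, whichever cells of these libraries they came from. In radial glia, the stem cells of the cortex, 18 of 19 measured genes were within 1.5-fold, and the Notch effector Hes5 was lower (640 and 358, log2 difference -0.82, with -0.23 by its other probe set). Sox2 (-0.034), Pax6 (0.19) and Nes (0.25) were among those within it. All 12 measured genes of intermediate progenitors, the dividing daughter cells of radial glia, were within 1.5-fold. Eomes, their marker transcription factor, lay at its edge with 355 in wild type and 525 in the null library (0.58). The brightest members, Rprm and Elavl2, differed by 0.090 and -0.18. Of 17 S phase genes, E2f1 (1.14) and the replication helicase subunit Mcm2 (0.82) were beyond 1.5-fold higher and none was lower, and their other measured probe sets gave 0.31 and 0.46. All 21 genes of the G2 and M phases were within 1.5-fold, with the proliferation marker Mki67 at -0.049 and Top2a at 0.31 (0.62 by its other measured probe set). The medians of these lists were -0.055, -0.0052, -0.085 and 0.021, all within the central 95% of matched random lists. With all probe sets averaged, radial glia were at -0.19, S phase at 0.081 and the G2 and M phases at -0.043. S phase was at 0.15 without the _s_at and _x_at types and at 0.032 with no filter. In the Notch pathway 15 of 16 genes were within 1.5-fold and the median was -0.11. Among Wnt targets and ligands, Sp5 (-1.20) and Wnt7a (-1.01) were lower and Fzd8 (0.67) and Lgr5 (0.65) were higher, and 14 genes were within 1.5-fold. The other probe sets of Wnt7a and Fzd8 gave 0.21 and -0.12, and with the floor at the median Sp5 was at -0.21 and Fzd8 at 0.57.

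Neuronal lists differed little between these libraries, which does not show that cortical cell types were unchanged. Among newborn and migrating neuron genes, Map1b was higher by 0.82, but its other probe set gave -0.15, and 18 of 19 were within 1.5-fold. The microtubule protein gene Dcx had a difference of -0.42. In deep-layer neurons Nxph4 was higher (200 and 436, 1.15) and 15 of 16 were within 1.5-fold. All 17 upper-layer genes were within 1.5-fold, with the brightest, Ptn and Mef2c, at 0.020 and -0.0071. The list medians were -0.092, -0.13 and -0.11, and 13 of the 17 upper-layer genes and 10 of the 16 deep-layer genes had negative differences. All 3 medians lay within the central 95% of random lists, the deep-layer median at the 2.55th percentile. With all probe sets of a gene averaged they were 0.039, -0.0045 and -0.027. The 7 genes reported as SoxC targets were within 1.5-fold, with Tubb3 at 0.24, Map2 at -0.014 (0.58 over its other probe sets) and a median of 0.12. In Cajal-Retzius cells, the earliest neurons of the cortical surface, Trp73 was lower (251 and 151, -0.72, and -0.48 with the floor at the median) and Reln had a difference of -0.45. All 16 measured interneuron genes were within 1.5-fold, with Gad1 at 0.31 and Maf at 0.090. In the striatum and ganglionic eminence list Drd1 was higher (1.30) and 11 of 12 were within 1.5-fold. The 8 hippocampal genes (Nrp2 0.039, Zbtb20 0.081) and the 10 genes of the thalamus and diencephalon (Zic1 -0.13, Tcf7l2 -0.17) were within 1.5-fold, although the other probe sets of Tcf7l2 gave 0.63. In axon guidance, Plxna2 lay just beyond the edge (0.59, but within 1.5-fold in 5 alternative settings, at 0.39 with all probe sets averaged and 0.53 to 0.57 in the others) and 27 of 28 genes were within 1.5-fold.

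Genes of the glutamatergic synapse were slightly higher as a list. Of 21 measured members, 18 had positive differences, and 3 were beyond 1.5-fold. These were the kinase gene Camk2a (302 and 477, 0.68, with 0.42 over its other probe sets), the adhesion gene Nlgn1 (119 and 181, 0.63) and the synaptic vesicle gene Syn1 (496 and 747, 0.61, but 0.55 with quantile normalization). The list median was 0.19, at the 99.7th percentile of random lists. Immediate early genes had a median of 0.21 over 10 measured members (98.4th percentile), with Jun higher (982 and 1617, 0.74, with 0.20 by its other probe set). Hypoxia and glycolysis genes had a median of 0.091 over 21 members (97.8th percentile), none beyond 1.5-fold, with Pgk1 at 0.054 and Aldoa at -0.037. With the sex-linked list, these were the 4 of 33 lists outside the central 95% of random lists. For lists of independent genes 1.65 would lie outside. Genes of 1 list can vary together and some lists share genes, so this number is no chance level for these lists. Nlgn1 lay near the array median and was at 0.048 with the floor there.

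**Figure D4:**
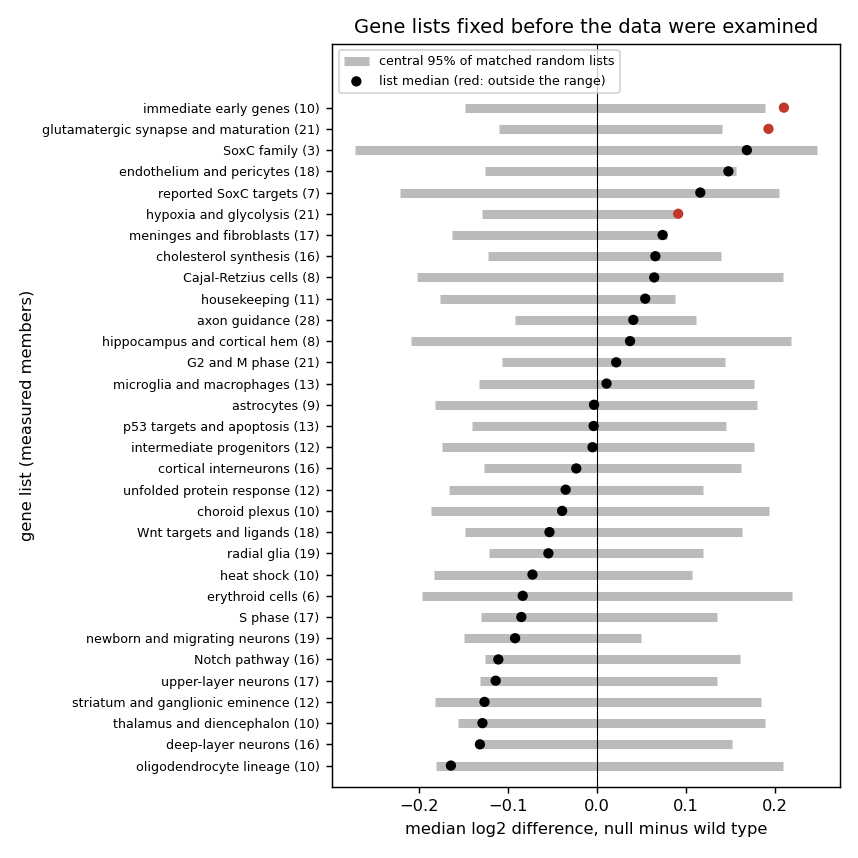
Median log2 difference (Sox11 null minus wild type) of 32 fixed gene lists, with measured members in brackets; grey bars span the central 95% of 10000 random lists matched on level, and red points lie outside it. Immediate early genes (0.21), glutamatergic synapse genes (0.19) and hypoxia and glycolysis genes (0.091) lie above their bars; the sex-linked list is not drawn.

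The fixed lists of vascular, meningeal, immune, blood, glial and choroid plexus cells lay within the central 95% of random lists. Endothelial and pericyte genes had a median of 0.15, with Tie1 (0.68), Cdh5 (0.63) and Pecam1 (0.60) higher, although Cdh5 was at 0.34 and Pecam1 at 0.57 with all probe sets averaged, and 14 of 18 positive. Meningeal and fibroblast genes had a median of 0.074 (96.8th percentile), with Foxc2 higher (0.64) and 16 of 17 within 1.5-fold. The median was 0.15 with quantile normalization and 0.16 with the loess trend removed. In microglia and macrophages Ctss was higher (0.68) and 12 of 13 were within 1.5-fold. In erythroid cells the beta-globin gene Hbb-b2 was lower (3042 and 1437, -1.06). Its difference was -0.0090 when averaged with its other probe set, which was unmeasured, and near-identical globin genes can share its probes. The 9 astrocyte genes (Gja1 -0.16, with 0.68 over its other probe sets, and Sparcl1 0.048), the 10 oligodendrocyte lineage genes (Pdgfra 0.26, Olig1 -0.22) and the 10 choroid plexus genes (Ttr -0.29, Aqp1 0.044) were within 1.5-fold.

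Epidermis, lens, tooth and pituitary lists had negative medians in the null library against wild type, and the muscle list did not. Of these added lists, second epidermis, lens, pituitary, teeth, cartilage and bone, and salivary glands lay below the 1st percentile of random lists, and muscle at the 99.9th. In a second epidermis list, 14 of 34 measured genes were beyond 1.5-fold lower and none was higher, with a median of -0.52 (quartiles -0.81 and -0.22). Ivl (-1.47), Krt1 (-1.38) and Crct1 (-1.34), all of the layers above the basal one, were the lowest, and Ivl was at -0.72 with the floor at the array median. All 8 lens and retina genes were below 0 and 6 were beyond 1.5-fold lower, with Crygd (-0.77), Crybb3 (-0.77) and Crygs (-0.71) leading and a median of -0.69. Of 4 tooth genes 3 were lower (Dspp -0.97, Ambn -0.80, Amelx -0.59) and the median was -0.70. With the floor at the array median Dspp was at -0.17 and the list at -0.38. The 3 measured pituitary genes Cga (-1.29), Gh (-1.26) and Pomc (-1.05) were all lower, and the list median went from -1.26 to -0.52 with no filter on low values. Among salivary and lacrimal gland genes Dcpp1 (-1.17, but 0.0094 with the floor at the array median) and Pip (-1.09, and -1.95 when averaged with its unmeasured other probe set) were lower. Of the 9 genes 7 were within 1.5-fold and 4 were above 0. That list's median was -0.26, and 0.0094 with the floor at the array median. In cartilage and bone Matn1 was lower (-0.90) and the median was -0.25. All 15 muscle genes were within 1.5-fold, with a median of 0.10.

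Xist and the Y-linked genes separated the libraries. The Xist signal was 17505 in wild type and 155 in the null library with the brightest probe set, and 2153 and 8.72 with another. Eif2s3y was at 0.814 in wild type and 1838 in the null library with 1 probe set, and at 28.0 and 72.3 with the other, below the median of both arrays. Kdm5d was at 14.6 and 446, and Uty at 21.8 and 617, with 25.6 and 305 by its other measured probe set. The other Kdm5d probe sets, unmeasured, were at 61.2 and 67.8 and at 6.74 and 3.87. Of the X-linked genes that escape inactivation, Kdm6a (-0.70), Kdm5c (-0.62), Eif2s3x (-0.44) and Ddx3x (-0.34) were lower in the null library, with a median of -0.53. The median was 0.027 with all probe sets of a gene averaged, unmeasured ones included. The other measured probe sets of Kdm6a (1) and Kdm5c (4) gave -0.62 and -0.48. The median difference of all 406 measured X-linked genes was -0.0012, and that of autosomal genes was 0.00023. The sex of the embryos is not among the labels, and the sex-linked genes differ along with the genotype in every comparison above.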

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

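The tests of head tissue, and the use of the basal bound against stratified epithelium in general, were chosen after the signals were seen. The tests of the second epidermis, basal epidermis and muscle lists and of the escape genes were written before the values of those lists were seen, but the basal epidermis tests came after the second epidermis values, which both use.

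Probe sets outside the gene comparison also differed: of 3068 measured probe sets naming no gene here or several, 52 were at least 2-fold higher in the Sox11-null library and 71 at least 2-fold lower. The largest of those higher was 1426438_at, at 8.20 in wild type and 1748 in the null library, at least 33.5-fold higher. This is the pattern of the Y-linked genes above. With no gene named for it here, whether it is sex-linked was not tested.

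Muscle, epidermal, salivary, lens and tooth genes were bright in both libraries. Tissue of the whole embryo is argued against by liver genes other than Ttr, whose median signals of 66.1 and 48.8 lay below the array medians. A candidate explanation is that both RNA samples held tissue of the head outside the brain, although the protocol describes an isolated cortex. Of head tissue genes 78.9% were above the median of both arrays, against 7.32% of trunk organ genes, or 14% with heart and Ttr. The head tissue lists were pooled, and the bounds set, after their values were seen. The shares therefore cannot tell that explanation from signal that such probe sets give whatever the tissue. Signal of that kind has no reason to be high, or to fall, together for the genes of a tissue, a premise not tested here. It is argued against for second epidermis genes, with 28 of 34 below 0 and 6 above (median -0.52, central range of random lists -0.12 to 0.084). So it is for muscle. All 15 muscle genes were measured, with median signals of 14230 and 15069, and the dimmest, Myog, was at 1204 and 1407. The 75th percentiles of the arrays were 583.5 and 602.6. All 8 lens genes were lower too (median -0.69, central range -0.20 to 0.15). That list was added after the first results, and related crystallin genes can share signal, so no conclusion is drawn from it. For salivary and tooth genes both explanations stay open. A sample exchanged before hybridisation was not tested and stays open.

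Genes of the epidermal layers above the basal one were mostly lower in the null library. Noise near the floor is argued against, since 20 of the 34 measured genes of the second epidermis list had wild-type signals above the 75th percentile. So is a larger share of head tissue with its muscle in the wild-type library, since the muscle median was 0.10. Signals this close to the top of the scale can be compressed. The muscle genes cannot speak for head tissue carried over without muscle, which was not tested and stays open. A larger share in wild type of epidermis as a whole, or of stratified epithelium in general, is argued against by the basal epidermis genes. Their median was -0.094 (quartiles -0.28 and 0.060, and also -0.094 over the 7 of 11 that are not widely expressed). The argument is limited, since other epithelia that express basal genes could hide a change. Members also differed, with Col17a1 at -0.58, Bnc1 at -0.47 and 4 of 11 above 0. Of the basal keratins, Krt14 was at -0.39, Krt5 at 0.11 and Krt15 at 0.19. The median of -0.52 over the second epidermis list, by itself, fell between the bounds written in advance. The gap of 0.43 between the basal and the second epidermis list goes with less of the late, cornified stage in the null library. That is a hypothesis from 1 embryo per genotype. For it, genotype, sex, pace of development and cornified layers alone carried into the wild-type sample stay open and untested. The members do not place the difference at the last stage alone. Krt1, which starts just above the basal layer, was at -1.38. The late genes Ivl, Lor and Lce1a1 were at -1.47, -0.69 and 0.026. The late genes Lce3c and Lce3a, picked for their large differences and dim in the null library, were at -3.22 and -2.26. Over Krt1, Krt10, Lor, Ivl and Flg the median was -1.47. The lens (-0.69), tooth (-0.70) and pituitary (-1.26) lists were lower as well, and an epidermal stage does not cover them.

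Xist was lower and Y-linked genes were higher in the null library. All 4 measured Y-linked probe sets, each measured through its null signal alone, were at least 2-fold higher. The 4 escape genes had a median of -0.53, so a difference of sex between the embryos may account for these genes. The escape-gene median was 0.027 when all probe sets of a gene were averaged, unmeasured ones included. The other measured probe sets of Kdm6a and Kdm5c gave -0.62 and -0.48. An effect of genotype on any other gene here is confounded with sex, which no value in 2 libraries separates.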

How the results depend on the processing

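No paired analysis was possible because each genotype has 1 array, and for the same reason no replicate could be left out. Of 346 alternative values of the counts, of Sox11 and of the fixed lists, 304 stayed close to the reported value (within 1.5 times for counts, within 1 SD of the probe sets for Sox11 and of random lists for list medians). Among single named genes 983 alternative values stayed within the technical SD, 55 moved further and 2 turned the sign of a difference beyond 1.5-fold. In all 28 of these gene values had another sign than reported, most of them within the technical SD of the reported value. Of 76 named genes beyond 1.5-fold, 30 were within it, or turned, in at least 1 alternative. Other sign changes were, with probe sets averaged, Sox12 -0.89, Tcf7l2 0.24, Gja1 0.51, Ccng1 0.30 and Myl4 -1.08, and Fgfr2 0.74 without the _s_at and _x_at types. Counts depended on the treatment of dim genes. With the floor at the median, 27 genes were 2-fold higher, 69 were 2-fold lower and 264 were 1.5-fold lower. With no filter these counts were 160, 212 and 796, with 722 genes 1.5-fold higher. With the filter at the 75th percentile they were 15, 47 and 139, with 134 1.5-fold higher. Fewer or more genes tested accounts for part of this by construction. Averaging all probe sets of a gene gave 139 genes 2-fold higher, 147 2-fold lower and a Sox11 difference of -1.78. Without X- and Y-linked genes and epithelial families, an alternative chosen after seeing the data, 70 genes were 2-fold lower.

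List medians depended most on the choice of probe sets. Averaging took in probe sets below the floor. The Sox12 value of -0.89, also the SoxC family median, took in 1456882_at, at 20.4 and 3.70 and below the floor on both arrays. Its measured probe sets gave 0.17 and -0.30. Hbb-b2, Pip and Myl4 had no other measured probe set. How far this moved the other lists was not tested. With all probe sets averaged, 13 of 33 fixed lists moved: SoxC family -0.89, radial glia -0.19, S phase 0.081, G2 and M phase -0.043, newborn neurons 0.039, deep layers -0.0045, upper layers -0.027, thalamus 0.10, axon guidance 0.15, Wnt 0.17, oligodendrocyte lineage 0.047, cholesterol synthesis -0.040 and sex-linked 1.86. Without the _s_at and _x_at types, S phase was 0.15, Notch -0.0060 and erythroid 0.19. With the filter at the 75th percentile, intermediate progenitors were -0.18, interneurons -0.11, striatum -0.24 and erythroid 0.13, and the sex-linked median turned to -1.62, since Xist and Uty alone passed that filter. That median was 4.84 with no floor, 1.35 with the floor at the median and 1.78 with no filter, and S phase was 0.032 with no filter. Quantile normalization gave -0.039 for newborn neurons and 0.15 for meninges, and the loess trend gave 0.16 for meninges. The glutamatergic synapse median stayed between 0.15 and 0.19, immediate early genes between 0.15 and 0.21, and hypoxia and glycolysis between 0.071 and 0.10 over all settings. The second epidermis median stayed between -0.61 and -0.42, lens between -0.71 and -0.65, and muscle between 0.063 and 0.20, while the pituitary median ran from -1.32 to -0.52 and the tooth median from -0.82 to -0.38. Of the list medians, 24 alternative values of fixed lists and 9 of added lists had another sign than reported. Beside the sex-linked list, those that turned a list outside the central 95% of random lists or a gene beyond 1.5-fold were Dcpp1 and the salivary list (0.0094 each with the floor at the median), Zfp991 (-0.19 with probe sets averaged) and the escape genes (0.027 with probe sets averaged).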

Other observations

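Stress and metabolic lists that the comparison did not lead with stayed within 1.5-fold in every measured member. These were the 13 p53 target and apoptosis genes (Ccng1 -0.11, Bcl2l1 0.021, median -0.0040), the 12 unfolded protein response genes (Hspa5 -0.17, Calr -0.16, median -0.035), the 10 heat shock genes (Hspa8 -0.16, Hsp90aa1 -0.048, median -0.073) and the 16 cholesterol synthesis genes (Hmgcs1 -0.18, Fdps 0.065, median 0.066). The 11 housekeeping genes had a median of 0.054, with Rpl13a at -0.23 and Rplp0 at -0.046. Other probe sets of Bcl2l1 and Ccng1 gave 1.31 and 0.56.

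Other tissue lists added after the first results held few measured members. Olfactory sensory neuron genes had a median of 0.027 over 6, with Gng13 lower (339 in wild type and 167 in the null library). Simple epithelium genes had a median of -0.049 over 8 (Cdh1 -0.26, Krt18 0.041), tongue genes of 0.023 over 3 (Krt4 -0.52, Krt13 0.023), cochlear genes of -0.039 over 3 (Otor -0.039, Coch -0.45), and heart genes of 0.43 over 3 (Tnnt2 0.43, with 0.65 by its other measured probe set, and Myl4 0.040), the last being genes that embryonic skeletal muscle also expresses. Among trunk organ lists, Sftpb (-0.71) and Foxf1 (0.85) of the lung list and Hoxd9 (-0.66) of the posterior Hox list were beyond 1.5-fold, but with the floor at the median they were at -0.28, 0.47 and -0.42, and Six2 of the kidney list (-0.13) and Cela1 of the pancreas and gut list (0.040) were the single measured members of theirs. Ttr was the single measured member of the liver list.

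A comparison not fixed in advance took the genes around Sox11. Of the 40 measured genes nearest to Sox11 by gene order in the GRCm38.p6 gene table, 20 on each side, 6 (15%) were beyond 1.5-fold, against 6.30% of all measured genes. With 1 embryo per genotype on a mixed background, the cause was not tested. The 18 bacterial and phage spike probe sets were all lower in the null library, by a median log2 difference of -0.33 (range -0.79 to -0.19).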
